A study of Danio rerio with 12 samples.

How the data were processed

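Polyadenylated RNA of whole zebrafish embryos was sequenced on an Ion Proton instrument, and each RNA sample came from a pool of 30 to 50 embryos with an RNA integrity number of at least 8, per the labels' protocols. The 12 libraries fell into 4 groups of 3, namely wild-type and miR-34a mutant embryos exposed to DMSO or to 1 µM camptothecin. Exposure began at 24 hours post fertilisation (hpf) and lasted 4 h, and the embryos were collected at 28 hpf. The labels give 0.005% DMSO for the controls and no DMSO content for the camptothecin-treated embryos, so a matched vehicle is not shown. The labels number the libraries within a group but do not say that they came from separate clutches or days, so the p-values measure the spread between these pools, which may be partly technical.

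The deposited table holds whole-number read counts per gene symbol for the 12 libraries, not normalised, with each column matched to its sample by genotype, treatment and replicate number. The authors' route to these counts is known only in part: per the submitters' processing notes the tools were Trim Galore 0.4.4, STAR 2.7, Bowtie2, Picard 2.5.0 and HTSeq 0.9.1, with the genome build danRer11. The gene annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Counts of genes with near-identical copies (ribosomal protein genes, actins, keratins, heat shock and globin genes), of overlapping genes and of antisense pairs are therefore uncertain at the level of the individual gene. The table lists 15265 genes, of which 875 had 0 counts in every library. Of the symbols, 13800 matched the supplied gene table of assembly GRCz12tu, which is a different build and was used for names, synonyms and gene order only, so no coordinates are given.

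Library totals ran from 13.5 to 27.9 M counts. A count of 0 in a group was given an upper limit of 3 counts over the group, and intervals on counts are exact 95% Poisson intervals that cover counting error only.

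Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group (11866 genes), libraries were scaled with TMM factors, and the robust quasi-likelihood model (glmQLFit, glmQLFTest) was fitted once to all 12 libraries as 4 group means with 8 residual degrees of freedom and no replicate block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold limit. The 6 contrasts were camptothecin against DMSO in each genotype, mutants against wild-type in each treatment, their difference (the interaction) and the genotype difference averaged over both treatments. Adjusted p-values of genes are from this edgeR quasi-likelihood test throughout. CPM values are TMM-scaled means ± SD over 3 libraries, except for the miR-34 genes, which the filter removed and which are given as CPM of the library total. Standard errors of log2 fold changes are the log2 fold change over the square root of the quasi-likelihood F statistic, and 95% intervals use the t distribution with the degrees of freedom of that test.

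The 25 gene lists, of pathways and of cell type markers, were fixed before the data were examined, as were the tests, the contrasts and the rule for named genes. They hold p53 targets, apoptosis machinery, DNA damage signalling and repair, topoisomerases, G1/S and DNA replication, G2/M and mitosis, canonical miR-34 targets from the mammalian literature, immediate early and AP-1 genes, inflammation and interferon, integrated stress and unfolded protein response, heat shock, ribosomal proteins, circadian clock, neural progenitors, differentiating neurons, skeletal muscle, heart, erythroid cells, myeloid leukocytes, endothelium, neural crest and pigment, lens and retina, epidermis, hatching gland and yolk syncytial layer, and notochord and cartilage. Of 907 entries, 13 were matched through a synonym. Lists with at least 5 tested members (all but the topoisomerases) were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) on voom values, with Benjamini-Hochberg adjustment over 24 lists and 6 contrasts. Camera with a correlation estimated per list and the rotation test fry were the alternatives.

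The rule for named genes took, per contrast, the 10 smallest p among called genes, and the 5 largest rises and falls among called genes with at least 1 CPM and no overlap of libraries. It also took up to 4 called members per list (or up to 2 as values where none was called) and a fixed set: mir34a, mir34b, mir34c, mdm2, cdkn1a, ccng1, bbc3, top1a, top1b, top1l, top2a, mycn, notch1a, sirt1 and bcl2a. The genes top1a, top1b and sirt1 were not analysed here, and 2 further genes that the rule names are not reported here. Of the list members that the rule takes, the text prints a part, chosen after the values were seen. The largest rises and falls were not defined for the interaction, which compares no pair of groups.

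The alternatives were DESeq2 1.42.0, limma-voom, DESeq2-type size factors, library totals without scaling, no filter, a stricter filter (at least 1 CPM in 3 libraries and a mean of at least 5 CPM), the replicate number as a block, a test against a 1.2-fold change (glmTreat), the compared groups only, and leaving out each library in turn. After the data were seen, the following were added: thinning every library to 13.5 M counts (and 10 further random thinnings), gene lists under library totals and thinning, other window sizes around the mutated locus, and 8 gene families defined by symbol. Neighbours of the miR-34a locus were the 100 tested genes on either side in the gene order of GRCz12tu, compared with all other placed genes by a 2-sided Fisher's exact test. The planned analyses of gene length, chromosome and seed matches in 3′ untranslated regions were not run, since a genome and annotation of the authors' build were not used here. Whether long genes lost more RNA than short ones under camptothecin is therefore open, for single genes and for lists.

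The procedure was tested on simulated data made from the libraries of the genotype comparison in DMSO (11782 genes). There edgeR recovered 49.3% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold, and 10 unchanged genes were called, which was 5.88% of the calls. The changed genes were drawn from those with a mean over 1 CPM in wild-type DMSO, so the recovery does not cover genes below that level. In a separate step with 11866 genes, camera called both of the 2 lists made with a change and 0 of 20 random lists. The genes were simulated independently of each other. That step therefore does not show how often camera calls unchanged lists whose members are correlated.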

Results

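RNA of whole zebrafish embryos at 28 hpf was compared between wild-type and miR-34a mutant animals, each treated for 4 h with DMSO or with 1 µM camptothecin (CPT), which traps topoisomerase I on DNA and causes DNA breaks. MicroRNA miR-34a is a known transcriptional target of p53 in vertebrates. The design asks which genes respond to DNA damage, which depend on miR-34a, and whether the response depends on miR-34a. Each of the 4 groups held 3 libraries. Total counts were 20.2 to 22.8 M in wild-type DMSO, 20.3 to 27.9 M in wild-type CPT, 15.0 to 22.4 M in mutant DMSO and 13.5 to 21.7 M in mutant CPT libraries.

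Treatment separated the libraries along the first principal component, which held 76.1% of the variance, and the second held 5.38%. Replicates of a group correlated across genes at a Spearman rho of 0.986 to 0.994, and every pair differed by more than sampling noise (chi-square per degree of freedom 7.70 to 67.2). The 3 wild-type CPT libraries stood apart in composition: the 10 most abundant genes held 10.7% to 12.3% of their counts, against 8.79% to 9.58% in the other 9 libraries. Their TMM factors were 0.835 to 0.962, against 1.01 to 1.09 elsewhere, and wild-type CPT libraries 1 and 3 were the pair farthest apart.

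**Figure D1:**
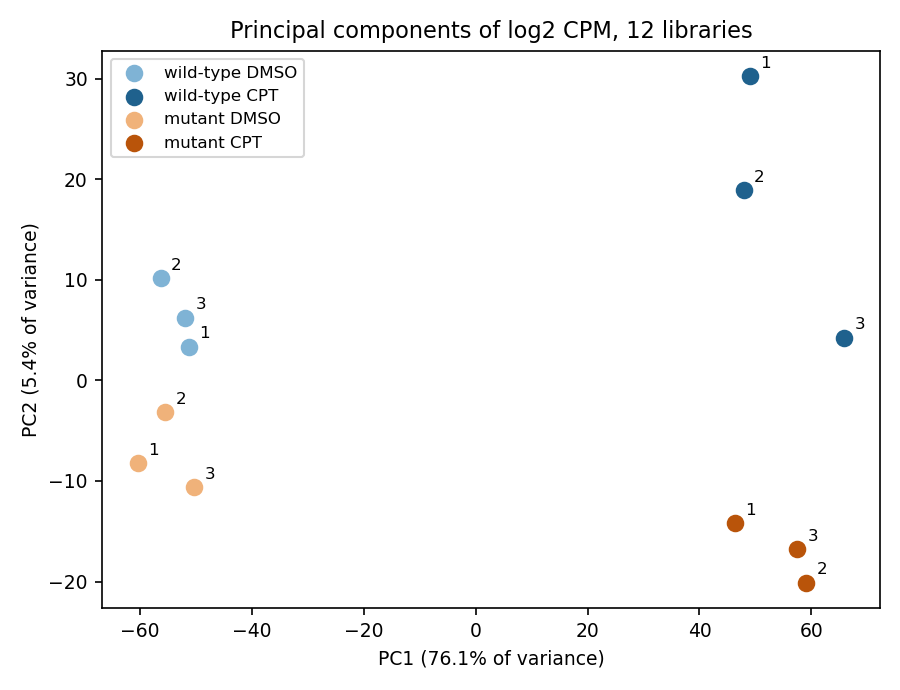
Principal components of log2 CPM in the 12 libraries, with PC1 (76.1% of the variance) on the x axis and PC2 (5.38%) on the y axis, each point a library marked with its replicate number and coloured by group. DMSO and CPT libraries lie on opposite sides of PC1, and wild-type libraries lie above mutant libraries of the same treatment on PC2.

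The mutated gene itself, listed as mir34 (a synonym of mir34a), was read out first. It had 0, 1 and 0 counts in the wild-type DMSO libraries and 9, 9 and 32 counts in the wild-type CPT libraries. All 6 mutant libraries had 0 counts. This was 0.648 ± 0.433 CPM (SD, n = 3) in wild-type CPT against 0.0154 ± 0.0267 in wild-type DMSO. The ratio of summed counts over summed library totals was 43.9, with a 95% counting interval of 7.52 to 1766. Wild-type CPT embryos were at least 11.4-fold higher than mutant CPT embryos, taking 3 counts over the group as the limit of a count of 0. The count columns of the mutants are named as a deletion of mir34a. The 0 counts there may follow from the deletion itself, so this comparison checks the genotype. The wild-type CPT libraries did not overlap with either group, and the 2-sided exact permutation p was 0.1 in both comparisons, the smallest that 3 against 3 libraries allow. Poly-A selected reads at this row come from a precursor and not from the mature microRNA. The genes mir34b and mir34c had 0 counts in all 12 libraries.

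**Figure D2:**
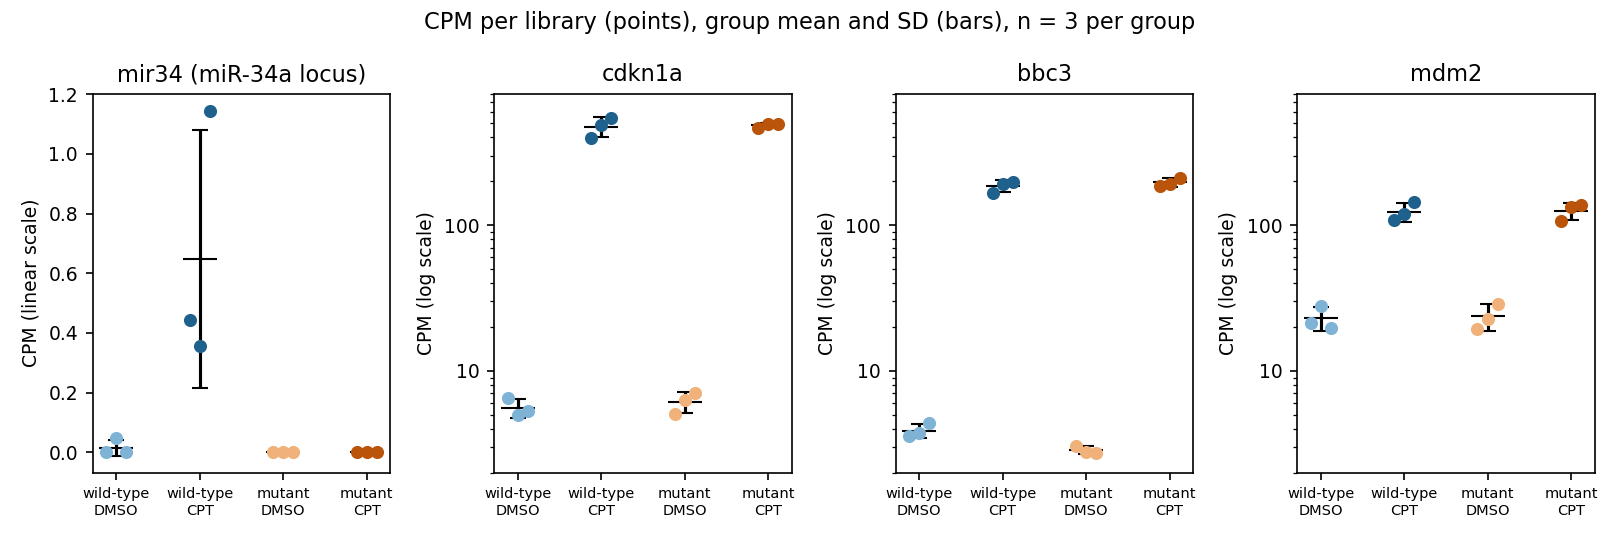
CPM of mir34 (linear axis, from library totals) and of cdkn1a, bbc3 and mdm2 (log axes), each point a library, with group means and SD bars (n = 3). Reads of mir34 appear in the 3 wild-type CPT libraries at 0.355 to 1.14 CPM and the mutants have 0, while the other 3 genes are higher under CPT in both genotypes.

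CPT raised the p53 pathway in wild-type embryos. The cell-cycle inhibitor cdkn1a (p21) rose from 5.58 ± 0.79 to 474 ± 75 CPM (SD, n = 3), a log2 fold change of 6.41 ± 0.16 (SE), and the pro-apoptotic bbc3 (Puma) rose from 3.90 ± 0.42 to 185 ± 17 CPM, by 5.57 ± 0.13. The p53 targets phlda3 (5.20) and gadd45aa (5.25) rose by similar amounts, the ubiquitin ligase gene mdm2 rose by 2.43 and ccng1 by 2.15. Expression of ccng1 was low, 0.209 ± 0.075 CPM in wild-type DMSO and 0.913 ± 0.37 in wild-type CPT. The interferon-stimulated ubiquitin-like gene isg15 had the largest rise, 7.71 ± 0.26, and the AP-1 genes fosab (5.91) and fosl1a (4.54) rose too. The edgeR adjusted p was 1.44e-17 for bbc3, 2.58e-17 for cdkn1a and phlda3, and at most 0.00166 for the other genes named here. The largest falls were in gfra2a (-5.71), msi2a (-5.68), luzp2 (-5.59), dacha (-5.01) and fndc3ba (-4.94). The other genes among the 10 smallest p were gtpbp1l (3.58), bmb (3.57), zgc:136826 (3.26, a p53 target listed as rps27l in the reference), aplnrb (3.07) and rhoub (2.61), all higher.

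In all, 7219 of 11866 tested genes (60.8%) changed in wild-type embryos, 3450 higher and 3769 lower, and of these 784 rose and 2001 fell by 2-fold or more. An unadjusted p under 0.05 was reached by 7599 genes, against 593.3 by chance. The balance rests on the scaling: with library totals in place of TMM factors, the median gene shifted by -0.23 on the log2 scale and the share of higher genes among the calls was 29.7% instead of 47.8%. No list called for CPT changed the sign of its median under that scaling. The median of apoptosis machinery in wild-type embryos was then 0.0052, against 0.23 with TMM. The other called lists there whose median moved by over 1.5 times were heat shock (0.22), inflammation and interferon (0.25), circadian clock (0.31), ribosomal proteins (0.41), hatching gland (0.11) and differentiating neurons (-0.62).

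Among pathway lists in wild-type embryos, 24 of 30 tested p53 targets rose and 1 fell (25 and 1 adjusted over the list alone), with a median log2 fold change of 1.33 and a camera adjusted p of 3.49e-11. Its p was 0.00189 with an estimated correlation (adjusted p = 0.168, not called). Apoptosis machinery rose, with 12 of 28 members higher and 4 lower (the same adjusted over the list alone), median 0.23, and camera adjusted p of 0.0159 (p = 0.0561 with an estimated correlation). Its leading genes were bbc3, casp8 (3.36), baxa (1.82) and endog (1.01), while the anti-apoptotic bcl2a fell by 2.21. Immediate early and AP-1 genes rose in 20 of 30 members with 0 lower (22 and 0 adjusted over the list alone), median 0.92, led by fosl1a, fosab, atf3 (2.82) and ier2a (2.00). Its camera adjusted p was 3.97e-07 (with an estimated correlation p = 0.0322, adjusted p = 0.399, not called). Inflammation and interferon genes rose in 10 of 27 members and fell in 4, also when adjusted over the list alone (median 0.46, camera adjusted p = 0.0305, p = 0.2 with an estimated correlation), led by isg15, socs3a (2.45), socs3b (1.43) and cebpb (1.04). That call was lost without wild-type DMSO library 3 (adjusted p = 0.0771). Heat shock genes rose in 14 of 22 members and fell in 1, also when adjusted over the list alone (median 0.46, camera adjusted p = 0.000927, p = 0.0937 with an estimated correlation), among them the collagen chaperone serpinh1a (1.89) and hsp70l (1.35). Ribosomal protein genes moved together: 56 of 69 rose and 0 fell (57 and 0 adjusted over the list alone), with a median of 0.65 and examples rpl4 (0.84) and rpl23 (0.79). Their camera adjusted p was 4.43e-09, and p = 0.216 with an estimated correlation. Circadian clock genes rose in 15 of 27 members and fell in 3 (15 and 4 adjusted over the list alone), with a median of 0.54, a camera adjusted p of 0.0395 and p = 0.197 with an estimated correlation. They were led by the light- and stress-inducible cry1aa (1.97), lonrf1l (1.13) and per2 (0.70). The circadian call was lost without wild-type DMSO library 1 (camera adjusted p = 0.0907), without wild-type CPT library 2 (0.0728) and with thinned libraries (0.0585).

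Genes of cell division fell. Of 43 tested G2/M and mitosis genes, 30 fell and 1 rose (the same adjusted over the list alone), with a median of -0.70 and a camera adjusted p of 6.40e-06 (with an estimated correlation p = 0.00818, adjusted p = 0.244, not called). They included the kinesins kif20a (-1.96) and kif11 (-1.42), the anaphase activator cdc20 (-1.72), the spindle checkpoint kinase ttk (-1.32) and top2a (-1.68). G1/S and DNA replication genes went both ways, with 14 of 50 higher and 20 lower (also when adjusted over the list alone), for example prim2 (-2.79) and pola1 (-1.69) against tk1 (1.35), and the list was not called (median -0.07, camera adjusted p = 0.856). DNA damage signalling and repair genes were also split, 15 higher and 15 lower of 47 (16 and 15 adjusted over the list alone), with parp3 at 2.04 and xrcc4 at -1.81, and the list was not called (adjusted p = 0.975). Its median was -0.09 and its mean -0.05, whereas the direction of the camera test was up. Of the 4 tested topoisomerase genes, top2b (-1.88) and top2a fell and top1l (0.77) and top1mt (0.33) rose, too few for a list test. The integrated stress and unfolded protein response list was not called (13 of 30 higher, 7 lower, and 13 and 8 adjusted over the list alone, median 0.24, camera adjusted p = 0.156), although slc3a2b rose by 0.81. The canonical miR-34 targets were not called under CPT either (13 of 50 higher, 25 lower, also when adjusted over the list alone, median -0.22, camera adjusted p = 0.171). Of that list, notch1a fell by 0.95, foxp1a by 1.52 and syt1a by 2.29, and fosl1a rose, while mycn was at 0.18 (edgeR adjusted p = 0.11).

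Markers of the nervous system, muscle and vessels fell in wild-type embryos, and whether these falls follow gene length was not tested. Neural progenitor genes fell in 22 of 28 members and rose in 3, also when adjusted over the list alone (median -0.70, camera adjusted p = 0.00025, p = 0.144 with an estimated correlation), among them msi1 (-1.81), cdh2 (-1.90) and pax6a (-1.18). Differentiating neuron genes fell in 19 of 34 and rose in 6 (20 and 6 adjusted over the list alone), with a median of -0.38, a camera adjusted p of 0.022 and p = 0.246 with an estimated correlation. Their examples were the RNA-binding protein elavl4, which went from 75.4 to 13.3 CPM (-2.50), and the transcription factor ebf3a (-3.91). Endothelial genes had the lowest median, -1.41, with 12 of 17 lower and 4 higher (12 and 5 adjusted over the list alone), and a camera adjusted p of 0.00832. An estimated correlation gave p = 0.0172 and adjusted p = 0.354, not called. The vascular growth factor receptors kdrl and flt4 fell by 2.66 and 2.60, and fli1a by 2.34. Skeletal muscle genes fell in 15 of 31 and rose in 2 (14 and 2 adjusted over the list alone), with a median of -0.61, a camera adjusted p of 0.0127 and p = 0.307 with an estimated correlation. They were led by the transcription factors mef2ca (-2.40) and mef2d (-2.01). Hatching gland and yolk syncytial layer genes rose in 14 of 27 members and fell in 3, also when adjusted over the list alone (median 0.34, camera adjusted p = 0.0205, p = 0.202 with an estimated correlation), with rbp4l at 0.73 and fgb at -1.35. With library totals the hatching gland list had a median of 0.11 and was not called (camera adjusted p = 0.0509).

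The remaining marker lists were not called in wild-type embryos. Lens and retina genes had a median of -0.35 (2 of 27 higher, 12 lower, also when adjusted over the list alone, camera adjusted p = 0.169), with rx2 at -2.19. Erythroid genes had 0 of 17 higher and 8 lower (0 and 7 adjusted over the list alone), median -0.31, adjusted p = 0.0656, and cahz fell by 1.76. Neural crest and pigment genes had a median of -0.49 (3 of 23 higher and 13 lower, also when adjusted over the list alone, adjusted p = 0.184), with pnp4a at -1.74. Myeloid genes had a median of -0.37 (4 of 13 higher and 6 lower, and 4 and 7 adjusted over the list alone, adjusted p = 0.692), with spi1b at -1.89. Epidermal genes had a median of 0.33 (13 of 26 higher and 6 lower, also when adjusted over the list alone, adjusted p = 0.322), with tp63 at -2.39 and krt96 at 0.74. Heart genes had a median of -0.02, a sign that was positive with DESeq2-type size factors (1 of 15 higher and 7 lower, also when adjusted over the list alone, adjusted p = 0.609). Notochord and cartilage genes had a median of -0.17 (4 of 20 higher and 7 lower, and 4 and 6 adjusted over the list alone, adjusted p = 0.555), with epyc at -0.77.

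The same treatment of miR-34a mutants asked whether the damage response needs the microRNA. In mutants cdkn1a rose from 6.13 ± 1.0 to 484 ± 16 CPM (6.29 ± 0.16), bbc3 from 2.85 ± 0.18 to 197 ± 13 CPM (6.11 ± 0.13), and phlda3 (5.31), gadd45aa (5.72), fosl1a (4.88), mdm2 (2.4) and ccng1 (2.08) rose as well. The edgeR adjusted p was 6.05e-18 for bbc3, 3.59e-17 for cdkn1a and at most 0.00308 for the others. The initiator caspase casp8 rose by 4.05, rhoub by 2.80, snx11 by 3.05 and rasl11b by 4.50, and the transcription factor meis1b fell by 2.97. The largest rises were isg15 (9.37 ± 0.30), cbln12 (fitted value 8.24, with 0 counts in mutant DMSO, so at least 37.2-fold) and si:dkey-204l11.1 (6.45). The largest falls were mycbp2 (-5.82), celf4 (-5.59), nlgn3a (-5.26), pax7a (-5.04) and nrxn2a (-5.01), of which celf4, nlgn3a and nrxn2a are genes of neurons and synapses. Of the fixed genes, top2a (-1.75), notch1a (-1.46) and bcl2a (-1.63) fell, top1l rose by 0.72, and mycn was at -0.08 (adjusted p = 0.474). In mutants 7146 genes changed, 3383 higher and 3763 lower, with 906 and 1955 of them by 2-fold or more. An unadjusted p under 0.05 was reached by 7605 genes.

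Lists in mutants moved as follows. The p53 targets had 24 of 30 members higher and 3 lower (median 1.36, camera adjusted p = 1.79e-10, with an estimated correlation p = 0.00233, adjusted p = 0.168, not called), and the counts were the same when adjusted over the list alone. Apoptosis machinery had 13 higher and 2 lower of 28, and 11 and 2 adjusted over the list alone (median 0.37, adjusted p = 0.00354, with an estimated correlation p = 0.0293, adjusted p = 0.399, not called), including baxa (1.92) and pmaip1 (3.65). Immediate early genes had 19 higher and 0 lower of 30, the same adjusted over the list alone (median 0.82, adjusted p = 9.70e-06, p = 0.0573 with an estimated correlation), including fosab (5.27) and atf3 (2.58). Inflammation and interferon genes had 14 higher and 1 lower of 27, the same adjusted over the list alone (median 0.68, adjusted p = 0.00306, p = 0.0873 with an estimated correlation), including socs3a (3.41) and irf1b (3.48). Heat shock genes had 13 higher and 1 lower of 22, also when adjusted over the list alone (median 0.41, adjusted p = 0.00354, p = 0.131 with an estimated correlation). Ribosomal protein genes had 46 higher and 0 lower of 69, also when adjusted over the list alone (median 0.63, adjusted p = 9.83e-09, p = 0.225 with an estimated correlation), including rps20 (1.29) and rps29 (0.93). G2/M genes had 27 lower and 2 higher of 43, and 28 and 2 adjusted over the list alone (median -0.68, adjusted p = 2.77e-06, with an estimated correlation p = 0.00652, adjusted p = 0.244, not called), including kif20a (-2.53) and cdc20 (-1.92).

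Of the marker lists in mutants, neural progenitors had 22 lower and 2 higher of 28 (median -0.96, camera adjusted p = 7.04e-05, p = 0.108 with an estimated correlation), with cdh2 at -2.12. Differentiating neurons had 22 lower and 3 higher of 34 (median -0.58, adjusted p = 0.00206, p = 0.14 with an estimated correlation), with elavl4 at -2.72. Skeletal muscle had 23 lower and 2 higher of 31 (median -0.76, adjusted p = 0.00018, p = 0.155 with an estimated correlation), with mef2d at -2.40. Endothelium had 12 lower and 4 higher of 17 (median -1.40, adjusted p = 0.00727, with an estimated correlation p = 0.0143, adjusted p = 0.343, not called), with kdrl at -2.58. Lens and retina had 16 lower and 1 higher of 27 (median -0.57, adjusted p = 0.00828, p = 0.272 with an estimated correlation), with rx2 at -2.27. For these 5 lists the counts were the same when adjusted over the list alone. Hatching gland (median 0.24, adjusted p = 0.0746) and circadian clock genes (median -0.03, mean 0.36, camera direction up, adjusted p = 0.24) were not called in mutants, and neither list was called in the interaction. The other lists not called in mutants were G1/S (adjusted p = 0.584), DNA damage signalling and repair (0.975, median 0.02 and mean -0.01, with a median of -0.04 under library totals), canonical miR-34 targets (0.0973), integrated stress (0.396), heart (0.643), erythroid (0.0544), myeloid (0.631), neural crest (0.169), epidermis (0.333) and notochord (0.214). With an estimated correlation 0 of 24 lists were called under CPT in either genotype, and 4 had an unadjusted p under 0.05 in each, whereas fry called 21 lists in wild-type embryos and 22 in mutants.

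**Figure D3:**
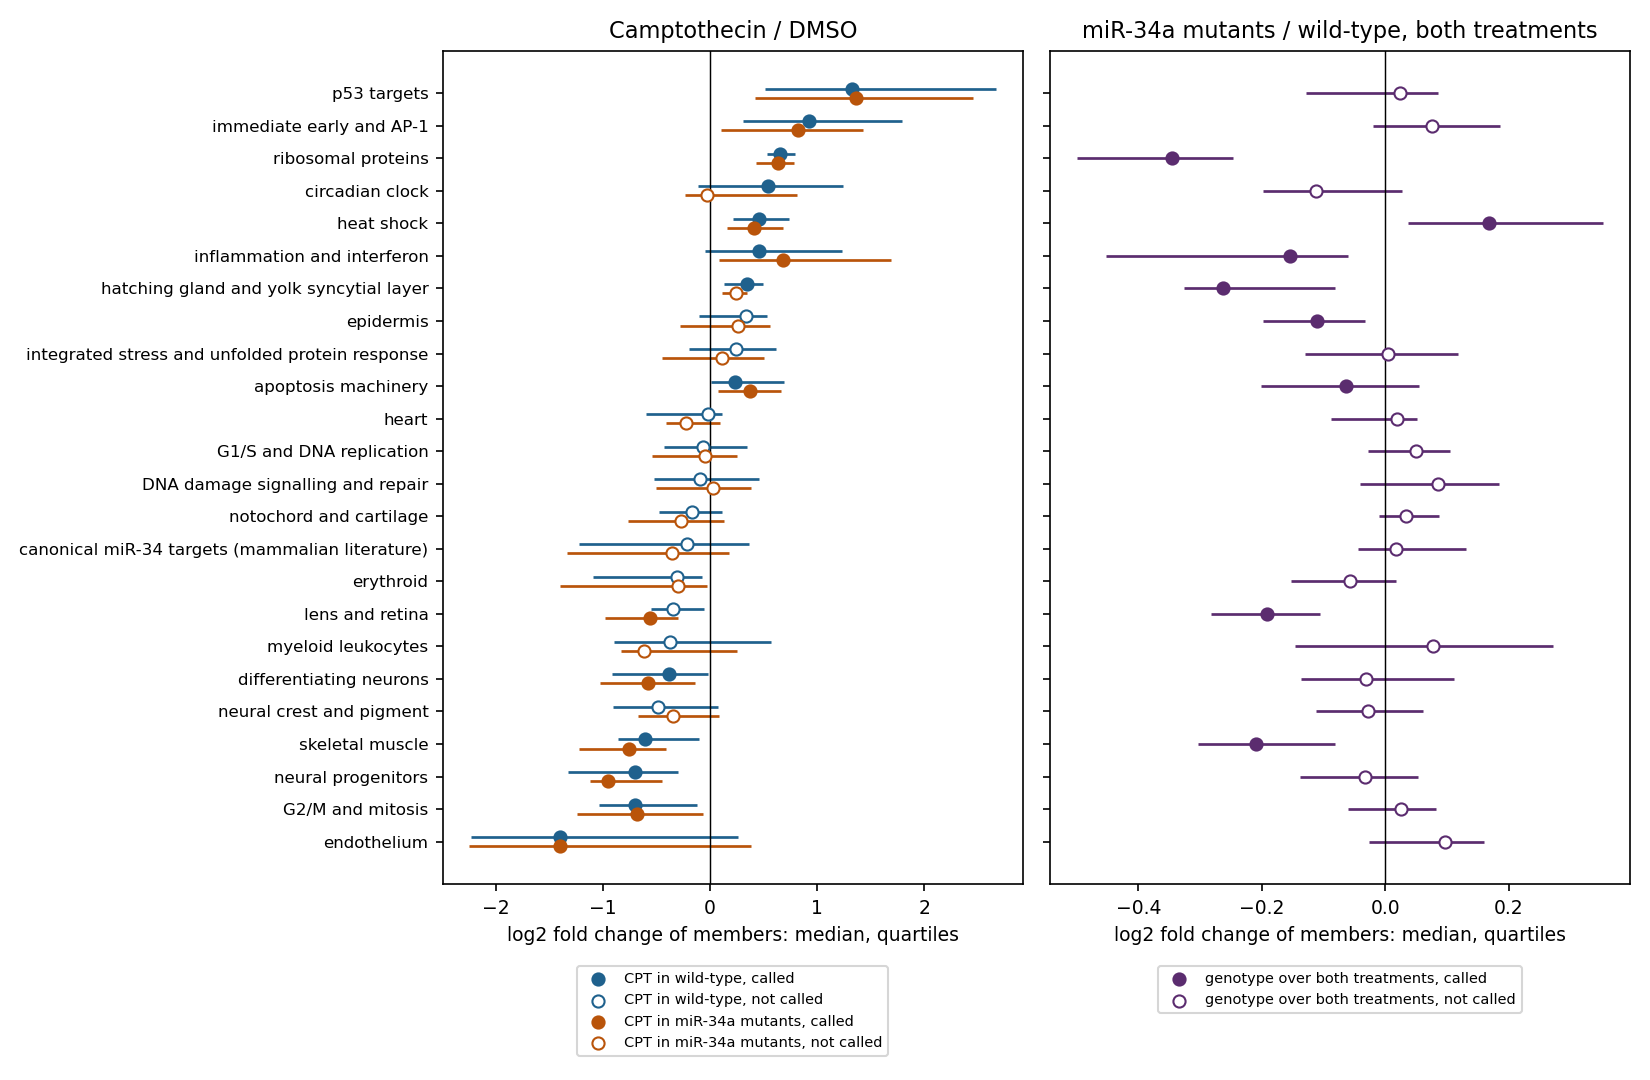
Median log2 fold change (points) and quartiles (lines) of the members of 24 gene lists, on the left for CPT against DMSO in each genotype and on the right for mutants against wild-type over both treatments, with filled points for lists called by camera at its preset correlation. The p53 targets are highest and endothelial genes lowest under CPT in both genotypes, and ribosomal proteins have the lowest median between genotypes, -0.35.

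The CPT responses of the genotypes had no library in common and ran parallel. Of the genes raised in wild-type embryos, 2606 (75.5%) were also called higher in mutants, against 984 from independent lists, and 3131 of those lowered (83.1%) were also called lower, against 1195. Opposite calls were made for 24 genes raised and 6 genes lowered in wild-type embryos. Across the 8598 genes called in either genotype, the log2 fold changes correlated at a Pearson r of 0.927 with a slope of 0.94, and across all 11866 genes at 0.911. Genes are not independent replicates, and the jackknife SE of r over the 12 libraries was 0.0264.

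**Figure D4:**
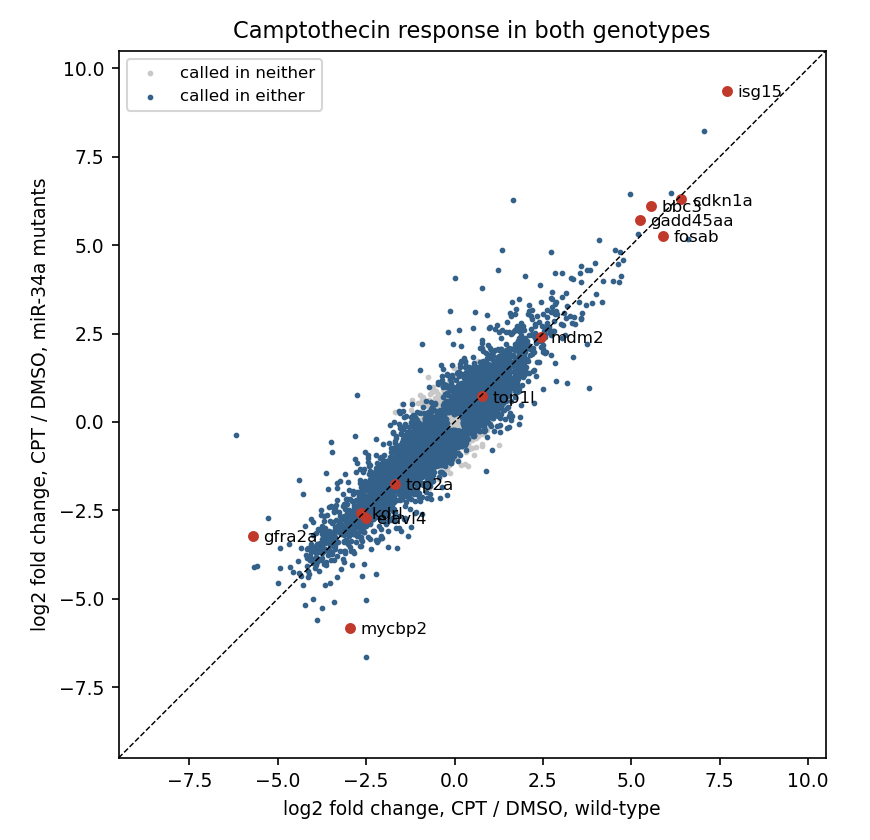
Log2 fold change of CPT against DMSO per gene in wild-type (x axis) and mutant embryos (y axis), with genes called in either genotype in blue, the rest in grey, some named genes in red and the line of equal change dashed. The cloud follows the line (r = 0.927), from mycbp2 and gfra2a at the lower end to isg15 at 7.71 and 9.37.

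Between genotypes, averaged over both treatments, a small number of genes differed by a large amount. The cochaperone ptges3a fell by 6.48 ± 0.24 in mutants, from 7.78 ± 0.77 to 0.0461 ± 0.044 CPM in DMSO and from 15 ± 2.2 to 0.265 ± 0.16 CPM in CPT. The mitochondrial isocitrate dehydrogenase subunit idh3g, at 7.89 ± 0.87 CPM in wild-type DMSO, had 0 counts in mutant DMSO, at least 155-fold lower, and 0.107 ± 0.054 CPM in mutant CPT. The gene szrd1 fell by 4.55 ± 0.20, and MGC174155 (-2.94), aldh8a1 (-2.92), smc1a (-3.13), a cohesin subunit, the complement genes c3b.1 (-2.07) and cfh (-1.59), and rimkla (-1.60) fell too. The transcription factors adnpb (2.00 ± 0.12) and stat6 (2.16), the Golgi protein gene slc35c2 (1.94), fam3a (1.95) and rnd1b (1.69) rose. The edgeR adjusted p was 3.06e-13 for ptges3a, 3.72e-12 for idh3g and at most 0.000416 for the others. Expression of smc1a was low, 1.79 ± 0.69 CPM in wild-type DMSO and 0.225 ± 0.043 in mutant DMSO. The similarly named smc1al was at 0.08 and not called (edgeR adjusted p = 0.673). Low in wild-type DMSO were also fam3a (0.790 ± 0.18 CPM, mutant DMSO 3.75 ± 0.26), rnd1b (0.742 ± 0.049, mutant DMSO 3.12 ± 0.88) and stat6 (1.18 ± 0.31, mutant DMSO 3.91 ± 0.43).

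In all, 254 genes differed over both treatments, 73 higher and 181 lower in mutants, and 49 of them by 2-fold or more (11 higher, 38 lower). An unadjusted p under 0.05 was reached by 1858 genes, against 593.3 by chance. The genes mdm2 (0.03), cdkn1a (0.09) and bbc3 (-0.18) were not called (smallest edgeR adjusted p 0.32). The fixed genes ccng1 (0.08), top1l (0.11), top2a (-0.07), mycn (-0.09), notch1a (-0.03) and bcl2a (0.15) were not called either (smallest edgeR adjusted p 0.57).

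The called genes clustered around the mutated locus. In the gene order of assembly GRCz12tu, 25 of the 200 tested genes nearest to the locus were called (12.5%, 7 higher and 18 lower), against 209 of 10790 other placed genes (1.94%), an odds ratio of 7.23 (95% interval 4.45 to 11.3) with a 2-sided Fisher's exact p of 7.63e-13. Of the genes named above, ptges3a, idh3g, szrd1, adnpb, stat6, fam3a, rnd1b, smc1a and aldh8a1 lie in this stretch. It held 10 of the 20 genes with the smallest p and 14 of the 49 genes that differed by 2-fold or more. Under CPT 65.5% of these 200 neighbours were called in wild-type embryos, against 61.1% of other placed genes, and 60.5% against 60.4% in mutants. The odds ratios were 1.21 (95% interval 0.895 to 1.65, Fisher's exact p = 0.214) and 1.00 (0.747 to 1.35, p = 1), so no clear difference was found.

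**Figure D5:**
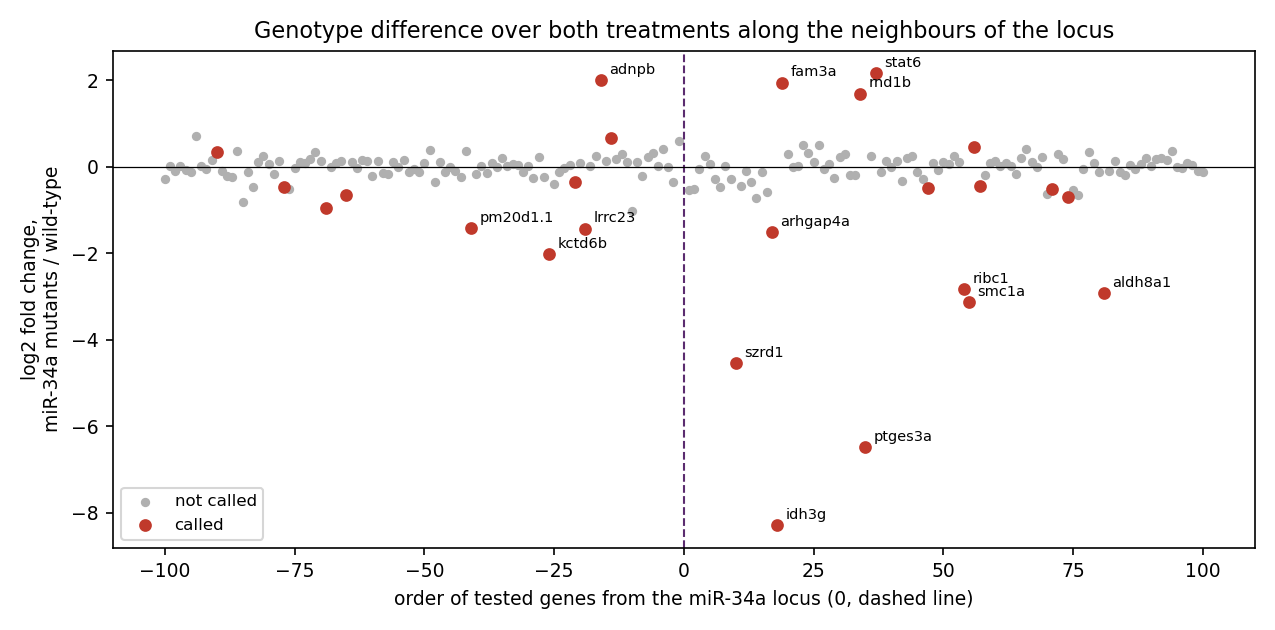
Log2 fold change of mutants against wild-type over both treatments (y axis) for the 100 tested genes on either side of the miR-34a locus in their order on assembly GRCz12tu (x axis, locus at 0), with called genes in red and the larger changes named. The 25 called genes include falls down to idh3g and rises of about 2 for stat6, adnpb and fam3a, among neighbours near 0.

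Of the lists, ribosomal protein genes were lower in mutants over both treatments: 11 of 69 fell and 0 rose, and 49 fell and 2 rose when adjusted over the list alone (median -0.35, camera adjusted p = 2.93e-29, with an estimated correlation p = 0.0388, adjusted p = 0.399, not called). Examples were rps18 (-0.69), rpl29 (-0.78), rps28 (-0.67) and rps14 (-0.47). Hatching gland and yolk syncytial layer genes fell in 7 of 27 members, and 16 fell and 1 rose adjusted over the list alone (median -0.26, adjusted p = 2.00e-10, with an estimated correlation p = 0.00846, adjusted p = 0.244, not called), with the apolipoprotein gene apoc2 at -0.50 and the antiprotease gene serpina1l at -0.57. Heat shock genes rose in 3 of 22 members, and in 9 adjusted over the list alone (median 0.17, adjusted p = 7.04e-05, p = 0.0536 with an estimated correlation), with hsp70l at 0.69. Skeletal muscle genes fell in 3 of 31 members, and in 10 adjusted over the list alone (median -0.21, adjusted p = 8.00e-06, p = 0.104 with an estimated correlation), with mylpfb and tnni2a.4 both at -0.33. Lens and retina (median -0.19, 1 of 27 lower, 2 adjusted over the list alone) had an adjusted p of 3.03e-05 (p = 0.118 with an estimated correlation). Neither the muscle nor the lens list was called in DMSO alone. At an unadjusted p under 0.05, muscle had 3 lower and 0 higher in DMSO, and 14 lower and 2 higher in CPT. Lens and retina had 0 lower and 1 higher in DMSO, and 11 lower and 0 higher in CPT. Epidermis (median -0.11, 1 of 26 lower, 5 adjusted over the list alone) had an adjusted p of 0.00124 (p = 0.11 with an estimated correlation), with krt8 at -0.47. This called member, krt8, is among the 200 tested genes nearest to the locus. Inflammation and interferon genes fell in 2 of 27 members, irf1b (-1.44) and nfkbiaa (-0.55), and in 5 adjusted over the list alone (median -0.15, adjusted p = 0.000958, p = 0.0802 with an estimated correlation). Apoptosis machinery had an adjusted p of 0.0202 (p = 0.0604 with an estimated correlation) with 1 of 28 lower, apaf1 (-0.31), 3 lower adjusted over the list alone, and a median of -0.06 that was 0.04 under library totals. That call was lost without wild-type CPT library 3 (camera adjusted p = 0.152) or mutant DMSO library 1 (0.0561). With library totals the medians were 0.27 for heat shock, -0.10 for skeletal muscle, -0.088 for lens and retina, -0.16 for hatching gland, -0.059 for inflammation and -0.00084 for epidermis.

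The canonical miR-34 targets, the list that loss of the microRNA addresses most directly, were not called over both treatments (median 0.02, camera adjusted p = 0.676, 1 of 50 higher and 1 lower, 1 and 2 adjusted over the list alone). The members called were ppp1r10 (0.35) and ldha (-0.46). The list was not called in DMSO (median 0.05, adjusted p = 0.497) or CPT alone (median -0.03, mean 0.01, adjusted p = 0.907). The p53 targets were not called between genotypes over both treatments (median 0.02, camera direction down, adjusted p = 0.676), with ppm1db at 0.58 and sesn1 at -0.27 among the called members. With an estimated correlation 0 lists were called over both treatments (2 at an unadjusted p under 0.05) and with fry 4. With library totals, 480 genes differed and 76.0% of them were higher, instead of 254 and 28.7%, since the median gene shifted by 0.10. With DESeq2 473 genes differed. Without wild-type CPT library 3, 632 genes were called, and fewer than 254 by over 1.5 times were called without wild-type DMSO libraries 2 (126) and 3 (131), wild-type CPT library 2 (144), mutant DMSO libraries 1 (161) and 3 (153), or mutant CPT libraries 1 (141), 2 (164) and 3 (138).

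In DMSO alone, where the embryos received no CPT, the genotypes differed at 71 genes, 23 higher and 48 lower in mutants. The genes idh3g (at least 155-fold lower), ptges3a (-7.09 ± 0.39), szrd1 (-5.04), MGC174155 (-3.37), smc1a (-2.98), aldh8a1 (-2.88), c3b.1 (-2.28) and cfh (-1.93) fell. The genes adnpb (2.38 ± 0.19), fam3a (2.24), slc35c2 (2.13), rnd1b (2.05) and stat6 (1.72) rose, and the edgeR adjusted p was 5.54e-10 for ptges3a and at most 0.00547 for the others. Further called genes were the interferon regulatory factor irf1b (-2.26), the NF-kappaB inhibitor nfkbiaa (-0.82), gmnn (-0.87), the chaperones hsp70l (1.05) and hspa5 (0.63), and apoc2 (-0.45). Not called were mdm2 (0.05), cdkn1a (0.15), ccng1 (0.11), bbc3 (-0.46, edgeR adjusted p = 0.194), top1l (0.14), top2a (-0.03), mycn (0.05), notch1a (0.22) and bcl2a (-0.14).

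The ribosomal protein list was lower in mutant DMSO embryos (median -0.35, camera adjusted p = 4.88e-19, p = 0.0818 with an estimated correlation), although 0 of its 69 members were called by edgeR, also when adjusted over the list alone, and 28 were lower at an unadjusted p under 0.05. Inflammation and interferon genes were lower (median -0.53, 2 of 27 lower, 8 adjusted over the list alone, adjusted p = 3.28e-05, with an estimated correlation p = 0.0386, adjusted p = 0.399, not called). Hatching gland genes were lower (median -0.21, 1 of 27, 5 adjusted over the list alone, adjusted p = 7.62e-06, with an estimated correlation p = 0.0369, adjusted p = 0.399, not called), and heat shock genes higher (median 0.12, 1 of 22, 4 adjusted over the list alone, adjusted p = 0.000326, p = 0.0765 with an estimated correlation). Apoptosis machinery (median -0.14, adjusted p = 0.00254, with an estimated correlation p = 0.0276, adjusted p = 0.399, not called) and epidermis (median -0.10, adjusted p = 0.00658, p = 0.165 with an estimated correlation) were lower with 0 called members, 0 and 2 adjusted over the list alone, and 8 and 6 lower at an unadjusted p under 0.05. In the mean per library, wild-type DMSO library 1 lay within the range of the mutant DMSO libraries for ribosomal proteins (-0.34, mutants -0.68 to -0.33), apoptosis machinery (-0.37, mutants -0.49 to -0.34) and heat shock genes (-0.20, mutants -0.25 to -0.06). With an estimated correlation 0 lists were called (3 at an unadjusted p under 0.05) and with fry 2. Without wild-type DMSO library 1, 196 genes were called, and without wild-type DMSO libraries 2 and 3 or mutant DMSO libraries 1, 2 and 3 there were 27, 28, 41, 24 and 35. With DESeq2 there were 186, and with the stricter filter 34.

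Under CPT the genotypes differed at 390 genes, 134 higher and 256 lower in mutants. Again ptges3a (-5.86 ± 0.30), idh3g (-6.25), szrd1 (-4.05), aldh8a1 (-2.97), ribc1 (-2.99), MGC174155 (-2.50) and rimkla (-2.07) fell, and stat6 (2.60), slc35c2 (1.76), fam3a (1.66) and adnpb (1.61) rose, joined by mir142a (2.63) and pank1a (1.88). Expression of mir142a was low, 0.154 ± 0.19 CPM in wild-type CPT and 1.12 ± 0.30 in mutant CPT, as was that of pank1a (0.371 ± 0.10 and 1.34 ± 0.55). The cardiac actin gene actc1a fell by 0.88 ± 0.11, from 896 ± 87 to 486 ± 19 CPM. The edgeR adjusted p was 1.28e-10 for ptges3a, 0.000213 for actc1a and at most 0.044 for the others. Again mdm2 (0.02), cdkn1a (0.03), ccng1 (0.04), bbc3 (0.09), top1l (0.08), top2a (-0.11), mycn (-0.22), notch1a (-0.29) and bcl2a (0.43) were not called, with a smallest edgeR adjusted p of 0.203.

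Skeletal muscle genes were lower in CPT-treated mutants (9 of 31, 12 adjusted over the list alone, median -0.43, camera adjusted p = 2.82e-06, p = 0.0896 with an estimated correlation), with acta1b at -0.80, actc1b at -0.74, casq1b at -0.54 and pvalb1 at -0.78. Ribosomal protein genes were lower (12 of 69, and 33 lower and 1 higher adjusted over the list alone, median -0.42, adjusted p = 4.86e-15, p = 0.117 with an estimated correlation), with rps18 at -0.82 and rpl17 at -0.76. Hatching gland genes were lower (7 of 27, 11 adjusted over the list alone, median -0.27, adjusted p = 7.61e-07, with an estimated correlation p = 0.0252, adjusted p = 0.399, not called), with serpina1l at -0.76 and rbp4l at -0.64. Lens and retina genes were lower (2 of 27, 5 adjusted over the list alone, median -0.32, adjusted p = 6.40e-06, p = 0.0925 with an estimated correlation), with cryba1b at -0.70. Heat shock genes were higher (2 of 22, serpinh1b at 0.58 and hsf1 at 0.40, and 5 higher and 1 lower adjusted over the list alone, median 0.09, adjusted p = 0.032, p = 0.234 with an estimated correlation). Circadian clock genes were lower with 0 called members, also when adjusted over the list alone, and 5 lower at an unadjusted p under 0.05 (median -0.21, adjusted p = 0.0235, p = 0.17 with an estimated correlation). The circadian call was lost without wild-type CPT libraries 2 (median -0.046, camera adjusted p = 0.166) and 3 (0.0709) or mutant CPT libraries 2 (0.151) and 3 (0.0501). The heat shock call was lost without the same 4 libraries (0.0931, 0.122, 0.115 and 0.0626). With library totals the medians were -0.23 for skeletal muscle, -0.22 for ribosomal proteins, -0.15 for lens and retina, -0.076 for hatching gland, -0.015 for circadian clock and 0.28 for heat shock genes. In the mean of the muscle list per library, wild-type CPT library 3 (-0.45) lay within the range of the mutant CPT libraries (-0.62 to -0.40), and wild-type CPT libraries 1 and 2, which had the lowest TMM factors, lay above it (-0.03 and -0.10). The ribosomal list had 0.75, 0.49 and 0.26 in wild-type CPT libraries 1, 2 and 3, whose TMM factors rose in that order (0.835, 0.877 and 0.962), against 0.01 to 0.23 in mutants. For lens and retina, wild-type CPT library 1 (-0.31) lay within the mutant range (-0.45 to -0.25), with libraries 2 and 3 at 0.14 and -0.07. Outside these lists, krt4 (-0.97), krt8 (-0.69), ascl1b (-0.54) and apaf1 (-0.61) fell and cdh1 (0.48) and top2b (0.56) rose.

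With library totals, 1195 genes were called for genotype in CPT and 91.0% of them were higher, against 390 and 34.4% with TMM, as the median gene shifted by 0.19. Without wild-type CPT library 3, 1045 genes were called, without libraries 1 and 2 of that group 179 and 65, and without mutant CPT libraries 1, 2 and 3 123, 91 and 90. With the compared groups alone 193 genes were called, and with DESeq2 691. With an estimated correlation 0 lists were called (1 at an unadjusted p under 0.05) and with fry 1. The genotype differences in DMSO and in CPT shared 7 higher and 23 lower genes, against 0.26 and 1.04 from independent lists, and correlated across the 431 genes called in either at 0.705, with the same sign in 59.9% of them. Across all genes the correlation was 0.226 and the same sign was found in 49.9%.

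The interaction asks directly whether the CPT response differs between genotypes. It was called for 19 genes, 3 higher and 16 lower, with 1797 genes at an unadjusted p under 0.05 against 593.3 by chance. The cardiac actin gene actc1a rose under CPT in wild-type embryos (0.56) and fell in mutants (-0.41), a difference of -0.97 ± 0.16. The heme synthesis gene alas1 rose more in wild-type embryos (1.41) than in mutants (0.59), a difference of -0.82. The genes wbp2nl (-0.82), ddx54 (-0.84), otx2a (-0.93), utp18 (-1.10) and syvn1 (-0.75) had lower responses in mutants, and the potassium channel gene kcnk6 (0.97), the adhesion gene cdh1 (0.74) and si:dkeyp-118b1.2 (0.84) had higher ones, each with an edgeR adjusted p of 0.0195. The replication helicase gene mcm7 was lower as well (-0.91). Not called were cdkn1a (-0.12), bbc3 (0.54), mdm2 (-0.03), ccng1 (-0.07), top1l (-0.05), top2a (-0.07), mycn (-0.26), notch1a (-0.51) and bcl2a (0.57), with a smallest edgeR adjusted p of 0.149. The 95% interval of the difference was -0.53 to 0.29 for cdkn1a and -0.50 to 0.44 for mdm2.

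Among lists, inflammation and interferon genes responded more in mutants (median difference 0.54, camera adjusted p = 0.0127, p = 0.142 with an estimated correlation), and skeletal muscle (-0.38, adjusted p = 0.0034, p = 0.242 with an estimated correlation) and lens and retina genes (-0.29, adjusted p = 0.0048, p = 0.247 with an estimated correlation) responded lower. In these lists 0 members were called by edgeR over all genes, and the lists had 8 higher, 2 higher and 8 lower, and 6 lower at an unadjusted p under 0.05. Adjusted over the list alone they had 5 higher, 1 higher and 7 lower, and 3 lower. Examples, as values, were irf1b (1.66), acta1b (-0.96) and cryba1b (-0.74). In DMSO 10 of 27 inflammation genes were lower and 0 higher in mutants at an unadjusted p under 0.05, and in CPT 2 were lower and 0 higher. The larger inflammation response in mutants thus started from a lower level in DMSO. The inflammation call was lost without wild-type DMSO library 2 (camera adjusted p = 0.0667) and with library totals (0.0868). The lens call was lost without wild-type CPT library 2 (0.115) or mutant DMSO library 1 (0.0509). With library totals the medians were 0.72 for inflammation, -0.19 for muscle and -0.11 for lens and retina. The p53 targets were not called in the interaction (median 0.07, mean 0.02, camera direction down, adjusted p = 0.975). With an estimated correlation and with fry 0 lists were called, and 0 had an unadjusted p under 0.05 in either. With library totals 7 genes were called, of which 85.7% were higher against 15.8%, as the median gene shifted by 0.17. With DESeq2 343 were called and against a 1.2-fold change 0 (1034 at an unadjusted p under 0.05). Without wild-type CPT library 3, 504 genes were called, without wild-type DMSO library 1 112, without mutant DMSO library 3 59 and without wild-type CPT library 1 31. Without wild-type DMSO library 3, 1 gene was called, and 0 without wild-type DMSO library 2, wild-type CPT library 2, mutant DMSO library 2 or mutant CPT libraries 1, 2 or 3 (1309 to 1705 at an unadjusted p under 0.05).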

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

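Tests chosen only after the result was seen were those of the canonical targets, of the ribosomal protein list, of other splits for the 2 CPT contrasts, the 10 further thinnings, and the comparison of the muscle medians with their SD; the tests of neighbours, depth and single wild-type CPT libraries and the other splits were chosen before their own results, those of depth and single libraries after the 19 genes and the median of -0.38 were seen.

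The CPT response differed between genotypes, by a test of the difference itself, for 19 genes. Lower in mutants were actc1a (-0.97), otx2a (-0.93), ddx54 (-0.84), alas1 (-0.82), wbp2nl (-0.82), syvn1 (-0.75) and utp18 (-1.10), and higher were kcnk6 (0.97), si:dkeyp-118b1.2 (0.84) and cdh1 (0.74), each with an edgeR adjusted p of 0.0195. By camera, the list of inflammation and interferon genes differed with a median of 0.54 (adjusted p = 0.0127), skeletal muscle with -0.38 (0.0034) and lens and retina with -0.29 (0.0048). None of these 3 lists was called with an estimated correlation or by fry.

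The interaction calls and the muscle list were weighed against depth, since mutant CPT libraries included the smallest. With every library thinned to the same count, 22 genes were called, among them the 19, and the muscle median was -0.30. In 10 further thinnings 19 to 31 genes were called and the median was -0.37 to -0.33 (SD 0.0168), a range that leaves out the first draw. The counts of called genes argue against depth for the calls. Thinning leaves the expected fold change of abundant genes nearly the same, so the medians say little about depth for the list. The muscle medians in this paragraph are of voom values, and the -0.38 above is of edgeR values. Without wild-type CPT libraries 1, 2 and 3 the muscle median was -0.22, -0.23 and -0.48, and 31, 0 and 504 genes were called. The highest median, -0.22, met the bound set before these values were seen, below -0.19. It did so by less than the SD of the 3 medians (0.148), a comparison added after the values were seen, and for that reason a part played by 1 library is left open and cannot be told apart from a genotype effect.

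The genes called between genotypes over both treatments were weighed against a stretch of the parental genome that travels with the mutation. Called genes were over-represented within 100 tested neighbours of the locus (odds ratio 7.23), and windows of 25, 50 and 200 genes, chosen after the data were seen, gave 9.02, 7.89 and 4.73. Sequence or expression differences of that stretch may account for genes such as ptges3a, idh3g, szrd1 and adnpb, and an effect of the mutation on its neighbours is not separated from it. The stretch held 10.7% of the placed called genes, so it does not account for most calls, and differences between the lines elsewhere stay open. Called lists also hold genes of the stretch. Among them were krt8 (-0.47) and krt5 (0.12) of epidermis, and rps26 (-0.50), rps21 (-0.82), rpl10 (-0.39) and rps12 (-0.04) of the ribosomal proteins. Apoptosis machinery holds casp9 (-0.59), dffa (-0.20) and bcl2l1 (0.03). Of these genes krt8 and rps26 were called, and the lists were not tested without such genes. The list of canonical miR-34 targets gave a camera adjusted p of 0.676, and a median near 0 over members that go both ways decides nothing about the loss of repression.

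The lower ribosomal protein genes in mutants were weighed against chance shifts of single libraries and against scaling. The mean of the list differed between genotypes within treatments by -0.36 on average (2-sided exact permutation p = 0.01, with 0.005 the smallest possible), although in DMSO wild-type library 1 (-0.34) lay below mutant library 2 (-0.33). The ribosomal list was picked after its camera result was seen, and the permutation p is not adjusted over the 24 lists tested. It therefore cannot decide on chance shifts of libraries. With library totals the median of voom values was -0.23, smaller in size than with TMM factors but of the same sign. The median gene shifted by 0.10 under that scaling, so scaling may carry a part of the difference. The sign argues against scaling as the whole of it. A difference in parents, collection or library batch that follows genotype, or in developmental pace, was not tested and stays open. Near-identical gene copies leave single genes uncertain.

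Other splits of the libraries were counted for each contrast. For CPT in wild-type embryos (7219 genes, highest other 0), CPT in mutants (7146, highest other 0), genotype in DMSO (71, highest other 1) and genotype in CPT (390, highest other 56), 1 of 10 splits gave as many genes, the real one, and 10 splits are too few for a share under 0.05. Over both treatments 1 of 100 splits, the real one, gave 254 genes or more (highest other 46), a share under 0.05. These were 100 of 200 possible splits, most of which mix the genotypes within groups and so widen the spread there. The share thus does not show how often chance alone gives 254 genes, and a batch that follows genotype would give the same result. For the interaction 4 of 100 splits gave 19 genes or more, the real one included, a share under 0.05 but close to it and with the same limits. The other splits among them gave 254, 46 and 37 genes. The highest other, 254, exchanged the genotypes of every CPT library and so turns the interaction into the genotype difference, a structure of the samples.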

How the results depend on the processing

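Thinning (11 draws in all), gene lists under library totals and thinning, and other neighbour windows were chosen after the data were seen; the other alternatives were planned.

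The counts of genes called for CPT stayed within 1.5 times of 7219 and 7146 under every alternative run, from 5608 to 7322 and from 5635 to 7224, and the correlation of the CPT responses was 0.90 to 0.931 with 1 library left out. Genotype counts moved more. With DESeq2 they were 186 in DMSO, 691 in CPT, 473 over both and 343 for the interaction. In the interaction DESeq2 gave no adjusted p to 9218 of 15265 genes, so it adjusted over fewer genes than edgeR. In the simulated DMSO comparison, unchanged genes were 12.4% of the DESeq2 calls, against 5.88% of the edgeR calls. With library totals the genotype counts were 1195 in CPT, 480 over both and 7 for the interaction. With glmTreat they were 26 in DMSO, 32 in CPT, 54 over both and 0 for the interaction (1034 at an unadjusted p under 0.05). The stricter filter gave 34 in DMSO, no filter 35 for the interaction, and the compared groups alone 193 in CPT, where fewer libraries set the spread. With 1 library left out they were 24 to 196 in DMSO (without mutant DMSO library 2 and wild-type DMSO library 1), 65 to 1045 in CPT (without wild-type CPT libraries 2 and 3) and 126 to 632 over both (without wild-type DMSO library 2 and wild-type CPT library 3). For the interaction they were 0 to 504, the highest without wild-type CPT library 3 and 0 without library 2 of wild-type DMSO, wild-type CPT or mutant DMSO or library 1, 2 or 3 of mutant CPT (1309 to 1705 genes at an unadjusted p under 0.05). Apart from fewer libraries in those settings, the cause was not tested.

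Among called lists, the median of apoptosis machinery over both treatments turned to 0.035 with library totals, and those of 3 added families turned as given under the other observations. The values that follow cover the named genes that were called or in the fixed set, and no other genes. Among them, signs reversed only for fixed genes that were not called. With library totals these were mycn in wild-type CPT (-0.048), top2a (0.094) between genotypes in CPT, mdm2 (0.13), cdkn1a (0.047), ccng1 (0.084), top1l (0.13) and top2a (0.11) in the interaction, and top2a (0.039), mycn (0.016) and notch1a (0.074) over both treatments, as the shift of all genes by the scaling implies. With limma-voom ccng1 was at -0.11 in DMSO, 0.19 in the interaction and -0.015 over both, and in CPT it was at -0.00065 with the replicate block and -0.024 thinned. The cause was not tested.

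With 1 library left out, genotype values in DMSO ranged from -0.12 to 0.21 for mdm2, -0.79 to 0.56 for ccng1, -0.090 to 0.040 for top2a, -0.0077 to 0.12 for mycn and -0.39 to 0.092 for bcl2a. In CPT they ranged from -0.073 to 0.13 for mdm2, -0.091 to 0.13 for cdkn1a and -0.20 to 0.35 for ccng1. In the interaction they ranged from -0.20 to 0.14 for mdm2, -0.52 to 0.83 for ccng1, -0.20 to 0.045 for top1l and -0.20 to 0.017 for top2a. Over both treatments they ranged from -0.052 to 0.11 for mdm2, -0.37 to 0.30 for ccng1 and -0.10 to 0.030 for notch1a.

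Of the 48 list calls, 48 were the same with the replicate block, 47 thinned, 46 with library totals and 31 with fry, and 0 with an estimated correlation (4, 4, 3, 1, 0 and 2 lists at an unadjusted p under 0.05 for CPT in wild-type embryos and mutants, genotype in DMSO and in CPT, interaction, and genotype over both). Camera compares a list with all other genes and scaling shifts both alike, so calls kept with library totals say little about the scaling. The apoptosis call over both treatments was kept although its median changed sign. Gene length, chromosome and seed matches were not run. Depth limits mir34, with 50 counts in wild-type CPT.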

Other observations

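Gene families defined by symbol were added after the data were seen, so all of the tests here were chosen after the results, and the camera p-values are adjusted over these families alone. With an estimated correlation 0 of these families were called in any contrast (smallest adjusted p 0.643), and p-values given for it below are unadjusted.

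Axon guidance receptors and ligands fell under CPT in both genotypes, and whether this follows gene length was not tested. In wild-type embryos 51 of 62 fell and 2 rose, and 52 and 2 adjusted over the list alone (median -2.06, camera adjusted p = 2.64e-14, p = 0.0505 with an estimated correlation). In mutants 55 fell and 2 rose, the same adjusted over the list alone (median -2.25, adjusted p = 1.66e-15, with an estimated correlation p = 0.0407, adjusted p = 0.643, not called). The neuropilins nrp2b (-3.38 in wild-type, -3.28 in mutants) and nrp1a (-3.53, -3.19), robo3 (-3.08, -3.34) and epha4b (-3.74, -3.71) were among them.

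Respiratory chain and ATP synthase genes rose in 49 of 79 members and fell in 2 in wild-type embryos, and 50 and 2 adjusted over the list alone (median 0.39, camera adjusted p = 5.44e-06, p = 0.14 with an estimated correlation). In mutants 41 rose and 2 fell, and 40 and 2 adjusted over the list alone (median 0.33, adjusted p = 3.06e-05, p = 0.175 with an estimated correlation), with cox8a at 0.77 in wild-type embryos. These medians were 0.15 and 0.27 with library totals. Translation factors rose in 40 of 63 members and fell in 6, also when adjusted over the list alone (median 0.41, adjusted p = 0.000131, p = 0.131 with an estimated correlation), with eif4a1a at 1.01 and eif3hb at -1.81. In mutants 26 rose and 9 fell, the same adjusted over the list alone (median 0.21, adjusted p = 0.0122, p = 0.297 with an estimated correlation). Their medians were 0.17 and 0.16 with library totals. Collagen genes fell in 14 of 25 members, and in 13 adjusted over the list alone (median -0.56, adjusted p = 0.00267, p = 0.332 with an estimated correlation), with col8a2 at -2.61. In mutants 21 fell, the same adjusted over the list alone (median -0.73, adjusted p = 7.86e-05, p = 0.216 with an estimated correlation). Proteasome genes rose in 19 of 45 members and fell in 6, also when adjusted over the list alone (median 0.24, adjusted p = 0.0122, p = 0.284 with an estimated correlation), and with library totals the median was 0.017. In mutants 19 rose and 4 fell, the same adjusted over the list alone (median 0.22, and 0.16 with library totals, adjusted p = 0.0392, p = 0.361 with an estimated correlation). The hox genes (median -0.17, adjusted p = 0.428), the SR and hnRNP splicing factors (-0.06, 0.953) and the zinc finger genes named znf (0.19, and -0.05 with library totals, adjusted p = 0.152) were not called in wild-type embryos.

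Between genotypes, respiratory chain genes were lower in mutants over both treatments (3 of 79, 23 adjusted over the list alone, median -0.13, and -0.026 with library totals, camera adjusted p = 7.68e-10, p = 0.0656 with an estimated correlation). They were also lower in DMSO (0 of 79, and 8 lower and 1 higher adjusted over the list alone, median -0.15, and -0.14 with library totals, adjusted p = 2.13e-05, p = 0.165 with an estimated correlation) and in CPT (10 of 79, and 12 lower and 2 higher adjusted over the list alone, median -0.17, and 0.021 with library totals, adjusted p = 1.37e-05, p = 0.157 with an estimated correlation). Translation factors were lower in CPT (8 of 63, and 8 lower and 1 higher adjusted over the list alone, median -0.14, and 0.060 with library totals, adjusted p = 0.000391, p = 0.155 with an estimated correlation). They were lower over both treatments too (4 lower and 1 higher, and 8 and 3 adjusted over the list alone, median -0.07, and 0.037 with library totals, adjusted p = 0.00833, p = 0.273 with an estimated correlation). In the interaction their median was -0.15, and 0.026 with library totals (0 members called, also adjusted over the list alone, adjusted p = 0.00235, p = 0.211 with an estimated correlation). Proteasome genes were lower in CPT (0 of 45, also adjusted over the list alone, median -0.13, and 0.058 with library totals, adjusted p = 0.0036, p = 0.218 with an estimated correlation) and over both treatments (1 of 45, the same adjusted over the list alone, median -0.055, and 0.044 with library totals, adjusted p = 0.00107, p = 0.167 with an estimated correlation). In DMSO the hox genes were lower (0 of 44, also adjusted over the list alone, median -0.12, adjusted p = 0.00651, p = 0.23 with an estimated correlation) and collagens higher (0 of 25, also adjusted over the list alone, median 0.15, adjusted p = 0.00833, p = 0.39 with an estimated correlation). Splicing factors were higher in DMSO (0 of 33, 2 adjusted over the list alone, median 0.12, adjusted p = 0.000785, p = 0.177 with an estimated correlation) and over both treatments (1 of 33, 2 adjusted over the list alone, median 0.084, and 0.18 with library totals, adjusted p = 0.00235, p = 0.216 with an estimated correlation).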
